A study of Homo sapiens with 6 samples.

How the data were processed

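Messenger RNA was profiled in 6 human libraries, all labelled as the breast cancer line MCF7. The labels call 3 of them dormant cancer cells (DCC) and 3 of them A-DCC, a name they do not spell out. Per the labels' protocols, RNA was taken from frozen cells with Trizol and made into libraries with an Illumina TruSeq RNA kit. The deposited table holds counts per gene, whole numbers that were not normalised. Its columns carry the same short codes as the sample titles, and each library was matched to its column by that code. One further column of per-sample counts matched no sample title, and this 1 unmatched column was not used here.

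The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and hg18, without saying what each was used for. The coordinates in the table were checked against GENCODE release 29 on GRCh38. Of 58503 gene identifiers present in both, 46269 (79.1%) had identical coordinates, so positions below are GRCh38 positions as the deposited table gives them. The program that made the counts, its handling of strand and of reads that fit several genes, and the annotation release are not given in the sources used here. Counts of near-identical genes (ribosomal proteins, histones, SERPINB3 and SERPINB4, CST1 and its relatives, HSPA1A and HSPA1B) and of overlapping genes on opposite strands (HSPE1 and HSPD1) are therefore uncertain. Gene symbols and biotypes were read from the table itself. It holds 61010 features, 334 of which are unannotated loci with no symbol or biotype.

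Library totals ran from 15705341 to 18253231 counts. Levels are given in CPM, counts scaled to a common library size. A gene at 1 CPM in a library has a counting error of 23.6% to 25.1% of its value, and 3 counts, used as the floor for a gene with no counts, stood for 0.168 to 0.189 CPM in a library. For folds against a group with no counts, the floor was 3 counts over the whole group. For genes with 1 to 3 counts in a group, the ratio of counts is given with an exact 95% interval conditional on their total. These intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

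Differential expression was computed with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Features passed edgeR's filterByExpr function with its default minimum count of 10 and minimum total of 15, which left 16613, of which 12752 were protein-coding. TMM factors scaled the libraries. The quasi-likelihood F test compared A-DCC with DCC, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are A-DCC over DCC. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM scaled by the TMM factors, as mean ± SD over 3 libraries per group.

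A total of 31 gene lists, the rule for naming genes and the tests were fixed before the data were examined. Of these lists, 29 had at least 5 measured members and were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Each list is given with the number of members past the gene test over all features and with the number adjusted over the list alone. The named genes are of 3 kinds. The first are the 6 largest rises and 6 largest falls among protein-coding genes past the threshold, with a mean of at least 5 CPM in a group and no overlap between the groups' libraries. The second are the 2 members of each list with the smallest adjusted p, where they passed. The third are 10 genes fixed in advance, namely MKI67, CDKN1A, CDKN1B, ESR1, PGR, NR2F1, BHLHE41, CCND1, ABCG2 and CD44. Other genes are said to have been chosen after their values were seen.

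Similarity between libraries was described with Pearson correlations and principal components of log2 CPM across the tested features. Genes are not independent replicates, so these correlations have no p-value. Pairs of libraries were also compared with a chi-square statistic per gene to look for a library deposited more than once, and no pair lay within sampling noise, so none were merged. The statistic was 2.71 to 3.24 for pairs within a group, apart from 70.7 and 68.6 for the A-DCC pairs that held library 3.

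The tests were checked on simulated counts drawn with the means of the DCC libraries and the spread and sizes of all the libraries. Changes were placed only in genes with an average log2 CPM above 2, so the recoveries below hold for such genes. In a comparison of 3 against 3 over 16082 simulated genes, the gene test recovered 25.4% of genes changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold, with 6 false calls among 149. Over 16126 simulated genes, camera called 10 of 10 lists shifted 1.5-fold and 0 of 30 unchanged lists. These lists held random genes drawn independently, so the check does not cover lists whose genes move together.

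Alternatives were DESeq2 1.42.0 size factors, library totals, no low-count filter, a filter of 5 CPM in 3 libraries, protein-coding genes alone, the replicate number as a block, each library left out, DESeq2's Wald test, limma-voom, stricter thresholds, an estimated correlation in camera, and the fry set test. Chosen after the data were seen were list counts without A-DCC library 3, an estimated correlation without that library, and lists corrected for gene length and GC content. GC content came from the GENCODE transcripts and was available for 16194 (97.5%) of the tested features. Figures were drawn with matplotlib 3.10.9.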

Results

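Gene expression was compared between 3 libraries that the labels call dormant cancer cells (DCC) and 3 libraries that they call A-DCC. Dormant cancer cells are cells that persist without dividing or while dividing slowly. The DCC libraries nevertheless held transcripts of cell division genes, with MKI67 at 284 ± 21 CPM and CENPF at 134 ± 9.55 CPM. Whether these cells divided was not tested. The series title speaks of waking dormant cancer cells, and the comparison asks how the cells called A-DCC differ from those called DCC in their messenger RNA. The DCC libraries held 15705341, 16766248 and 15836904 counts, and the A-DCC libraries held 16893930, 17615687 and 18253231 counts. Between 19175 and 19747 genes had at least 5 counts in the DCC libraries, against 17097 to 18410 in the A-DCC libraries. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

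All 6 libraries are labelled MCF7, a breast cancer line used as a model of luminal, oestrogen receptor positive disease. Most of 9 markers of that state were near zero in the libraries labelled MCF7. ESR1, the oestrogen receptor, stood at 0.549 ± 0.196 CPM in DCC and 0.993 ± 0.455 CPM in A-DCC (SD, n = 3 each). PGR, the progesterone receptor, had 5 counts in DCC and 0 in A-DCC and was too low to test. GATA3, KRT19, TFF1, TFF3 and SPDEF, chosen after their values were seen, lay under 2 CPM in every library as well, so 7 of 9 luminal breast markers did. The other 2, FOXA1 and GREB1, were at 7.05 to 21.9 CPM and 1.73 to 4.94 CPM. Outside these 9, the keratins KRT7, KRT8 and KRT18 of the luminal identity list were abundant. They were also chosen after their values were seen, and stood at 470 ± 2.6, 1270 ± 32.4 and 629 ± 15.8 CPM in DCC. Of 8 basal or triple-negative markers, 5 were at 5 CPM or more in every library, among them EGFR with 170 ± 2.49 CPM in DCC and KRT17 with 369 ± 12.2 CPM. The basal keratins KRT5 and KRT14 were near zero, with highest levels of 0.351 and 1.01 CPM, and LAMC2 was at 4.49 to 30.3 CPM. CDKN2A and MTAP, neighbouring genes on chromosome 9 that are deleted in MCF7, were at 177 to 253 CPM and 59.8 to 83.9 CPM. The labels are therefore used below as names of libraries.

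The libraries separated by group. The first principal component held 76.7% of the variance and parted DCC, at -70.54 to -69.26, from A-DCC, at 64.47 to 80. Correlations across genes were 0.991 to 0.992 within DCC, 0.992 between A-DCC libraries 1 and 2, and 0.911 to 0.918 between the groups. A-DCC library 3 stood apart from the other A-DCC libraries, with correlations of 0.97 and 0.971 and a value of 60.43 on the second component, which held 15.6% of the variance. Its share of mitochondrial ribosomal RNA was 0.524% of counts, against 1.12% and 1.06% in A-DCC libraries 1 and 2 and 1.6% to 1.81% in DCC.

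**Figure D1:**
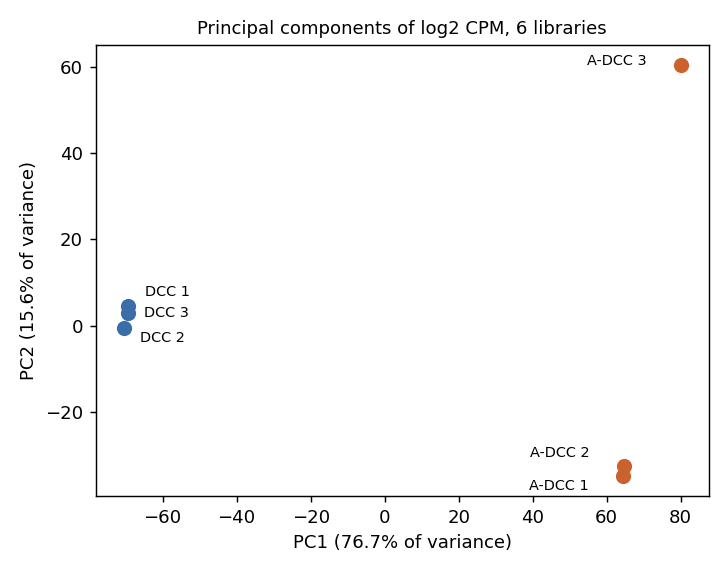
Principal components of log2 CPM for the 6 libraries, with DCC in blue and A-DCC in orange; each point is a library. PC1 (76.7% of variance) parts the groups, and PC2 (15.6%) parts A-DCC library 3, at 60.43, from A-DCC libraries 1 and 2, at -34.83 and -32.58.

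MMP1, SFTPB, CST1, IL1RL1, TNFAIP6 and SERPINB3 fell most from DCC to A-DCC among the genes named by size of change. MMP1, the interstitial collagenase (chromosome 11, 102789919 to 102798160), went from 48.1 ± 1.54 CPM in DCC to 0 counts in A-DCC, at least 835-fold lower. SFTPB (a surfactant protein), CST1 (a cystatin), IL1RL1 (the receptor for interleukin 33) and TNFAIP6 (a hyaluronan-binding protein) also had 0 counts in A-DCC and were at least 201-fold, 137-fold, 117-fold and 96-fold lower. SERPINB3, a protease inhibitor with a near-identical neighbour, had 538 counts in DCC and 1 in A-DCC, a ratio of 576 (95% interval 103 to 22800), and the single count lay in A-DCC library 3, without which the group held 0 counts. The largest rises were in GABRA1, LGSN, SLC12A3, PZP, GALNTL6 and SRRM4. GABRA1, a subunit of the GABA-A receptor (chromosome 5, 161847063 to 161899981), had 2 counts in DCC and 408 in A-DCC, a ratio of 191 (95% interval 52.4 to 1580). SLC12A3, a sodium-chloride cotransporter, rose from 0.185 ± 0.127 to 26.03 ± 10.1 CPM, and PZP, a protease inhibitor of the alpha-2-macroglobulin family, rose from 0.287 ± 0.0319 to 29.7 ± 7.34 CPM. LGSN, GALNTL6 and SRRM4 rose by 7.29 ± 0.82, 6.45 ± 0.37 and 6.44 ± 0.94 on the log2 scale (SE), and the SRRM4 value was 7.68 without DCC library 3. Each of the 6 genes that rose was lowest within A-DCC in library 3. GABRA1 was at 2.635 CPM there, against 10.14 and 10.56 CPM in A-DCC libraries 1 and 2. LGSN was at 5.09 CPM against 17.26 and 19.84 CPM, and SRRM4 at 2.17 CPM against 11.19 and 9.95 CPM.

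These 12 genes had edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 8.77e-06 for MMP1 to 0.00118 for SRRM4. In that test 8205 of 16613 features changed (49.4%), 4023 of them higher and 4182 lower in A-DCC. With a log2 fold change above 1 in size as well, 3787 remained, 1565 higher and 2222 lower. A total of 50 genes had 0 counts in every A-DCC library and at least 1 CPM in DCC, and 0 genes had the opposite pattern.

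Gene lists were tested with camera, and 14 of 29 passed with the preset correlation, 6 higher and 8 lower in A-DCC. None of the 14 passed with an estimated correlation, where 5 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.11. That correlation is estimated from the spread within groups of 3 libraries, so failing this test does not show that a list was unmoved. With the preset correlation camera also called 11 to 18 lists in the 9 other ways of splitting the libraries 3 against 3. Each of those splits mixes the groups unevenly and so keeps part of the difference between them.

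**Figure D2:**
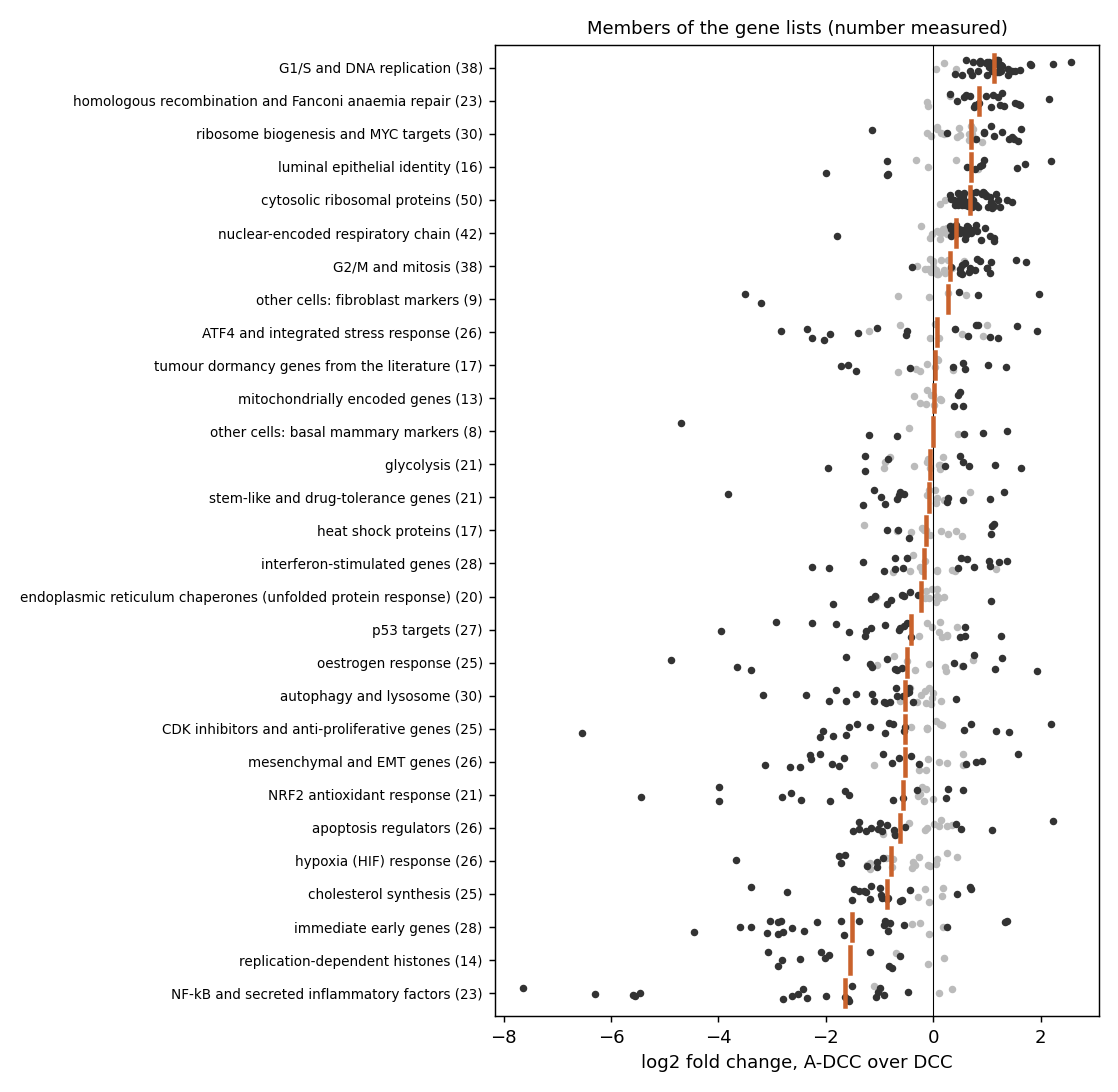
Log2 fold change (A-DCC over DCC) of each measured member of the 29 tested lists, with the number measured in brackets; dark points passed the gene test, grey points did not, and orange bars are medians. G1/S and DNA replication lies highest with a median of 1.14, and NF-kB and secreted inflammatory factors lowest with a median of -1.64.

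Genes of DNA replication rose together in A-DCC. Of 38 measured genes of G1/S and DNA replication, 35 rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 fold change of 1.14 (camera, Benjamini-Hochberg adjusted p = 2.02e-13, and adjusted p = 0.213 with an estimated correlation). DHFR, which makes tetrahydrofolate for nucleotide synthesis, rose from 24.02 ± 1.58 to 142 ± 26.4 CPM, and CHAF1A, a subunit of the factor that loads histones behind the fork, rose from 45.1 ± 0.516 to 119 ± 5.96 CPM. Of 23 genes of homologous recombination and the Fanconi anaemia pathway, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.86 (camera, Benjamini-Hochberg adjusted p = 7.73e-08, and adjusted p = 0.213 with an estimated correlation). FANCI rose from 89.4 ± 5.43 to 257 ± 19.1 CPM and BRCA1 from 43 ± 2.38 to 132 ± 13.1 CPM. The 4 named genes had edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 3.19e-05 to 4.08e-05.

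Mitotic genes moved less evenly. In G2/M and mitosis, 17 of 38 genes rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.31 (camera, Benjamini-Hochberg adjusted p = 0.00743, and adjusted p = 0.766 with an estimated correlation). A-DCC library 3 decided this list: its median shift from DCC was 0.65, against 0.04 and 0.15 in A-DCC libraries 1 and 2. Without it 17 genes rose and 12 fell, the median was 0.05 and camera's Benjamini-Hochberg adjusted p was 0.171. CENPF, a kinetochore protein, rose from 134 ± 9.55 to 388 ± 82.6 CPM and ASPM, a spindle pole protein, from 71.3 ± 7.21 to 235 ± 63.2 CPM. MKI67, the proliferation marker Ki-67, rose from 284 ± 21 to 499 ± 148 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0107), at a log2 fold change of 0.81. It missed the threshold without DCC library 2 at a similar 0.79 (adjusted p = 0.0531), and passed without A-DCC library 3 at 0.55 (adjusted p = 7.86e-15). Replication-dependent histones, whose transcripts mostly lack poly(A) tails, had 14 of 21 members measured. Of these 0 rose and 11 fell (0 and 12 adjusted over the list alone), with a median of -1.55 (camera, Benjamini-Hochberg adjusted p = 0.000327, and adjusted p = 0.405 with an estimated correlation). The median shift was -1.3, -1.34 and -1.93 in A-DCC libraries 1, 2 and 3. The share of mitochondrial ribosomal RNA was likewise lower in A-DCC and lowest in library 3. Whether the histone fall reflects expression or the RNA that entered the libraries was not tested. The histone H2B genes H2BC4 and H2BC8 fell from 33.2 ± 2.16 to 4.47 ± 0.933 CPM and from 14.5 ± 1.33 to 2.05 ± 0.242 CPM.

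Among 25 CDK inhibitors and anti-proliferative genes, 5 rose and 13 fell (5 and 13 adjusted over the list alone), and the list did not pass (median -0.52, camera, Benjamini-Hochberg adjusted p = 0.111). Leaving out A-DCC library 3 gave 8 higher and 14 lower, and a median of -0.33. CDKN2B, the CDK4 and CDK6 inhibitor p15, fell from 125 ± 3.85 to 30.2 ± 1 CPM, and the transcription factor gene KLF6 fell from 199 ± 3.97 to 54.5 ± 3.19 CPM. CDKN1A, which encodes p21, fell from 512 ± 11.7 to 173 ± 81.2 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00782), with 78.9 CPM in A-DCC library 3 and 222 and 218 CPM in the other A-DCC libraries. CDKN1B, which encodes p27, was at 128 ± 2.65 and 139 ± 30.3 CPM and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.561), but passed at a log2 fold change of 0.30 without A-DCC library 3 (adjusted p = 6.23e-07). CCND1, cyclin D1, was at 75 ± 5.81 and 126 ± 75 CPM (adjusted p = 0.119 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with 213 CPM in A-DCC library 3. It passed with no low-count filter (log2 fold change 0.81, adjusted p = 0.00991), without A-DCC library 1 (1.00, adjusted p = 0.0479) and without A-DCC library 3 (0.15, adjusted p = 0.0246).

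Ribosomal protein and respiratory chain genes were higher in A-DCC. Of 50 cytosolic ribosomal protein genes, 48 rose and 0 fell (49 and 0 adjusted over the list alone), with a median of 0.69 (camera, Benjamini-Hochberg adjusted p = 2.89e-15, and adjusted p = 0.227 with an estimated correlation). RPS9 rose from 267 ± 10.1 to 690 ± 39.9 CPM and RPL10A from 268 ± 7.46 to 623 ± 15.2 CPM. Reads of these genes can be shared with their processed pseudogenes. Of 42 nuclear-encoded respiratory chain genes, 29 rose and 1, NDUFV2, fell (33 and 2 adjusted over the list alone), with a median of 0.43 (camera, Benjamini-Hochberg adjusted p = 1.22e-06, and adjusted p = 0.18 with an estimated correlation), or 34 and 2 with A-DCC library 3 left out. UQCRB of complex III rose from 111 ± 1.25 to 243 ± 11.4 CPM and ATP5PO of the ATP synthase from 21.2 ± 1.75 to 46.6 ± 2.94 CPM. Of 13 mitochondrially encoded genes, 4 rose and 0 fell (3 and 0 adjusted over the list alone), led by MT-CO1 and MT-CO2 with log2 fold changes of 0.51 ± 0.09 and 0.56 ± 0.11. That list did not pass (median 0.02, camera, Benjamini-Hochberg adjusted p = 0.498), and without A-DCC library 3 its members split into 4 higher and 5 lower, with a median of 0.00.

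In ribosome biogenesis and MYC targets, 12 of 30 genes rose and 1, NOP2, fell (12 and 1 adjusted over the list alone), with a median of 0.71 (camera, Benjamini-Hochberg adjusted p = 0.00662, and adjusted p = 0.766 with an estimated correlation). FBL, the methyltransferase of small nucleolar RNPs, rose from 85.2 ± 3.04 to 208 ± 3.44 CPM. NPM1, a nucleolar protein, rose from 766 ± 24 to 2127 ± 836 CPM. A-DCC library 3 weighed on this list too, with a median shift of 1.32 against 0.17 and 0.24 in A-DCC libraries 1 and 2. Without it 18 genes rose and 7 fell, the median was 0.23 and camera's Benjamini-Hochberg adjusted p was 0.0537.

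Inflammatory and signal-induced genes fell in A-DCC. In NF-kB targets and secreted inflammatory factors, 0 of 23 genes rose and 20 fell (0 and 21 adjusted over the list alone), with a median of -1.64, which stayed at -1.64 with TNF, at 0 counts in A-DCC, set to its bound (camera, Benjamini-Hochberg adjusted p = 1.24e-07, and adjusted p = 0.11 with an estimated correlation). IL1B, which encodes interleukin 1 beta (chromosome 2, 112829751 to 112836816), fell from 190 ± 7.51 to 2.39 ± 1.47 CPM, and the cytokine gene LIF fell from 78.3 ± 4.5 to 15.3 ± 0.576 CPM. Of 28 immediate early genes, 3 rose and 20 fell (3 and 20 adjusted over the list alone), with a median of -1.52 (camera, Benjamini-Hochberg adjusted p = 1.67e-05, and adjusted p = 0.569 with an estimated correlation). DUSP6, a phosphatase that acts on ERK and is induced by it, fell from 65.3 ± 3.34 to 2.99 ± 0.396 CPM, and IER5 fell from 201 ± 2.52 to 45.1 ± 3.15 CPM. The 3 that rose were NR4A3, DUSP2 and MYC, and the counts became 5 higher and 22 lower with A-DCC library 3 left out. The 4 named genes that fell had edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 3.65e-06 to 3.95e-05.

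Lysosomal, antioxidant and sterol genes also fell. In autophagy and lysosome, 1 of 30 genes (TFEB) rose and 18 fell (1 and 18 adjusted over the list alone), with a median of -0.52 (camera, Benjamini-Hochberg adjusted p = 4.9e-05, and adjusted p = 0.11 with an estimated correlation). The lysosomal proteases CTSL and CTSB fell from 1508 ± 24.6 to 169 ± 39.3 CPM and from 1190 ± 31.4 to 309 ± 35.4 CPM. Of 21 genes of the NRF2 antioxidant response, 3 rose and 12 fell (3 and 13 adjusted over the list alone), with a median of -0.56 (camera, Benjamini-Hochberg adjusted p = 0.00143, and adjusted p = 0.213 with an estimated correlation). HMOX1, which degrades haem, fell from 400.1 ± 20.1 to 25.1 ± 4.44 CPM, and FTH1, the ferritin heavy chain, from 5843 ± 261 to 1056 ± 123 CPM. In cholesterol synthesis, 3 of 25 genes (PMVK, FDPS and LSS) rose and 17 fell (3 and 17 adjusted over the list alone), with a median of -0.86 (camera, Benjamini-Hochberg adjusted p = 0.00107, and adjusted p = 0.405 with an estimated correlation). MSMO1, a sterol C4-methyl oxidase, fell from 360 ± 12.1 to 34.4 ± 3.18 CPM, and SC5D, a sterol desaturase, from 46.9 ± 1.8 to 19.2 ± 0.772 CPM. The 6 named genes had edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 3.65e-06 to 6.12e-05.

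A-DCC library 3 also decided the hypoxia list, which did not pass without it. Of 26 genes of the HIF response, 0 rose and 8 fell (0 and 7 adjusted over the list alone), with a median of -0.79 (camera, Benjamini-Hochberg adjusted p = 0.0135, and adjusted p = 0.766 with an estimated correlation). PFKFB3, a regulator of glycolysis, fell from 128 ± 4.54 to 38 ± 2.07 CPM, and P4HA1, a collagen prolyl hydroxylase, from 546 ± 13.5 to 175 ± 61.7 CPM. The list's median shift from DCC was -2.02 in A-DCC library 3 and -0.39 in both other A-DCC libraries. Without library 3, 8 genes rose and 15 fell, the median was -0.40 and camera's Benjamini-Hochberg adjusted p was 0.0752. NDRG1 and CA9, chosen after their values were seen, were at 202 and 17.6 CPM in A-DCC library 3, against 1618 to 1663 and 141 to 144 CPM in the other A-DCC libraries and 2630 ± 38.9 and 185 ± 8.37 CPM in DCC.

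Glycolysis genes went both ways, with 6 of 21 higher and 4 lower (5 and 4 adjusted over the list alone), a median of -0.05, and a camera direction upward (Benjamini-Hochberg adjusted p = 0.829). Without A-DCC library 3 that list had 10 higher and 9 lower genes and a median of 0.00. LDHB rose by 1.63 ± 0.15 and HK1 fell by 0.84 on the log2 scale. Among 17 heat shock genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, median -0.13, camera, Benjamini-Hochberg adjusted p = 0.799), and the chaperonin genes HSPD1 and HSPE1, which overlap on opposite strands, had log2 fold changes of 1.08 ± 0.24 and 1.13 ± 0.25. The heat shock median shift was 0.80 in A-DCC library 3 but -0.56 and -0.45 in the other A-DCC libraries, and without library 3 the list held 4 higher and 11 lower genes. The ATF4 and integrated stress response list had 8 higher and 9 lower of 26 (10 and 9 adjusted over the list alone). Its median was 0.07, its mean was -0.20 and camera's direction was down (Benjamini-Hochberg adjusted p = 0.928). PSAT1, of serine synthesis, rose by 1.56 ± 0.13 on the log2 scale while ATF3 fell from 164 ± 3.26 to 22.9 ± 4.56 CPM, and without A-DCC library 3 the list had 14 higher and 11 lower genes. Its median was then 0.28 and camera's direction turned up (Benjamini-Hochberg adjusted p = 0.464), as its median shift was 0.26 and 0.28 in A-DCC libraries 1 and 2 but -0.69 in library 3. Of 20 endoplasmic reticulum chaperone genes, 1 (CRELD2) rose and 9 fell (1 and 10 adjusted over the list alone, median -0.22, camera, Benjamini-Hochberg adjusted p = 0.0668), among them SYVN1 and XBP1, which fell by 1.08 and 0.86 on the log2 scale. Without A-DCC library 3, 4 of these genes were higher and 12 lower.

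In mesenchymal and EMT genes, 4 of 26 rose and 14 fell (4 and 15 adjusted over the list alone), with a median of -0.53 (camera, Benjamini-Hochberg adjusted p = 0.0284, and adjusted p = 0.213 with an estimated correlation). SNAI1, a repressor of E-cadherin, fell from 58.3 ± 3.17 to 9.2 ± 0.968 CPM, whereas CALD1, an actin-binding protein, rose from 114 ± 6.36 to 342 ± 3.05 CPM. Of 16 measured luminal identity genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.70, camera, Benjamini-Hochberg adjusted p = 0.279). The median shift of this list was 0.70 and 0.64 in A-DCC libraries 1 and 2 but 0.01 in library 3. The tight junction gene CLDN4 fell from 96.1 ± 4.65 to 23.9 ± 2.77 CPM while TFAP2C, a transcription factor gene, fell from 71.5 ± 2.15 to 39.3 ± 1.39 CPM. ESR1 did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.186), but passed without A-DCC library 3 at a log2 fold change of 1.18 (adjusted p = 0.0194). Oestrogen response genes split into 6 higher and 10 lower of 25 (6 and 10 adjusted over the list alone, median -0.49, camera, Benjamini-Hochberg adjusted p = 0.285). AREG, the EGFR ligand amphiregulin, fell from 221 ± 4.22 to 7.52 ± 1.56 CPM, and CTSD, cathepsin D, from 482 ± 21.5 to 157 ± 24.8 CPM. Of 21 stem-like and drug-tolerance genes, 5 rose and 9 fell (5 and 9 adjusted over the list alone, median -0.08, camera, Benjamini-Hochberg adjusted p = 0.498), or 8 and 12 with a median of -0.30 when A-DCC library 3 was left out. CD44, the hyaluronan receptor, fell from 663 ± 10.7 to 267 ± 63.8 CPM and KDM5B, a histone demethylase, from 169 ± 2.52 to 86.8 ± 11.6 CPM. ABCG2, a drug efflux pump, fell from 54.5 ± 1.68 to 34.8 ± 11.3 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0354). Its call was lost when DCC library 1, 2 or 3 or A-DCC library 1 or 2 was left out, at Benjamini-Hochberg adjusted p of 0.0962, 0.0913, 0.102, 0.103 and 0.0921. The log2 fold change, -0.64 with all libraries, was -0.67 to -0.46 in these 5 cases, and -0.93 without A-DCC library 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.73e-15).

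Tumour dormancy genes from the literature did not move as a list. Of 17 measured, 5 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of 0.03, a mean of -0.12 and an upward camera direction (Benjamini-Hochberg adjusted p = 0.829). The dormancy regulator NR2F1 fell from 25.8 ± 1 to 19.2 ± 0.86 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00953), at a log2 fold change of -0.43, and missed the threshold with no low-count filter at -0.37 (adjusted p = 0.0683). BHLHE41 was at 2.62 ± 0.693 and 2.09 ± 0.0377 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.339). TGFBR3, a TGF-beta co-receptor, rose from 22.3 ± 2.55 to 45.3 ± 6.26 CPM and AXL, a receptor tyrosine kinase, from 107 ± 4.62 to 157 ± 5.85 CPM. Without A-DCC library 3 the list had 6 higher and 7 lower genes, a median of -0.11 and a downward camera direction (Benjamini-Hochberg adjusted p = 0.784).

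**Figure D3:**
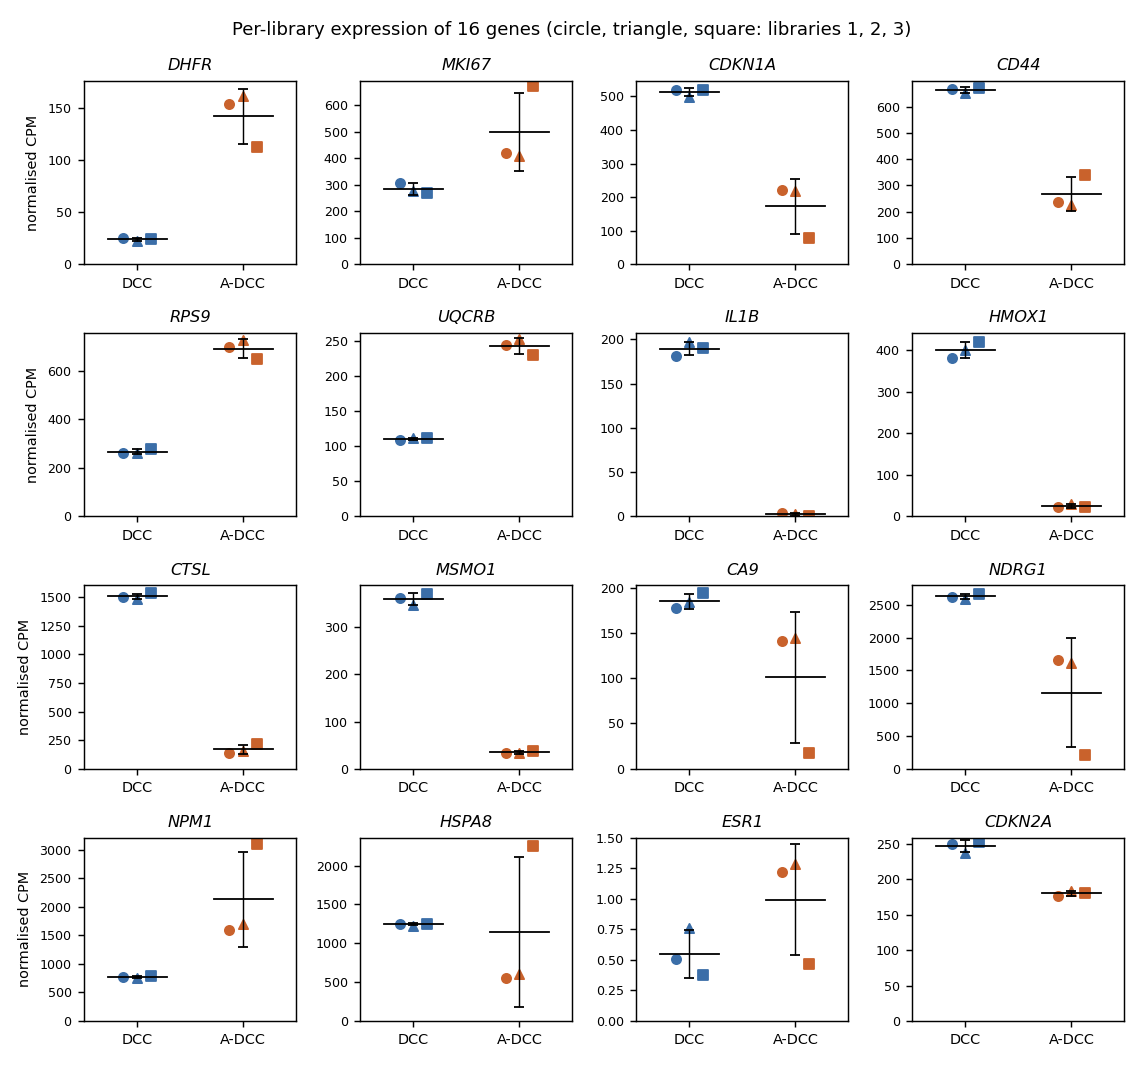
Expression of 16 genes in each library, in TMM-scaled CPM; circles, triangles and squares are libraries 1, 2 and 3 of a group, bars are means and whiskers are SD. DHFR rises from 24.02 to 142 CPM and HMOX1 falls from 400.1 to 25.1 CPM, while NDRG1 and HSPA8 differ more within A-DCC than most genes shown.

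Of 27 p53 targets, 4 rose and 14 fell (4 and 15 adjusted over the list alone, median -0.42, camera, Benjamini-Hochberg adjusted p = 0.107). GADD45A fell from 161 ± 6.3 to 21.2 ± 2.56 CPM and TNFRSF10B, a TRAIL receptor, from 308 ± 4.18 to 139 ± 9.34 CPM. Of 26 apoptosis regulators, 4 rose and 12 fell (4 and 13 adjusted over the list alone, median -0.62, camera, Benjamini-Hochberg adjusted p = 0.0698), and PMAIP1, which encodes the BH3 protein NOXA, fell from 95 ± 5.7 to 33.9 ± 2.2 CPM. Interferon-stimulated genes split into 8 higher and 8 lower of 28 (8 and 8 adjusted over the list alone, median -0.17, camera, Benjamini-Hochberg adjusted p = 0.799), with IRF7 down by a log2 fold change of -2.25 ± 0.15 and OAS3 up by 1.03 ± 0.10. Without A-DCC library 3 that list had 8 higher and 15 lower genes and a median of -0.27. Its median shift from DCC was -0.22 and -0.33 in A-DCC libraries 1 and 2 but 0.04 in library 3.

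Lists fixed in advance as markers of other cell types showed no shared direction. Of the basal mammary list, KRT17 (131 to 383 CPM) and EGFR (167 to 272 CPM) were abundant in every library. That list therefore cannot show whether other cells were present. Basal mammary markers split into 3 higher and 3 lower of 8 (3 and 3 adjusted over the list alone, median 0.01, mean -0.46, camera direction up, Benjamini-Hochberg adjusted p = 0.928), with CAV1 and MYLK higher by 1.37 ± 0.14 and 0.92 ± 0.10 on the log2 scale. Fibroblast markers split into 3 higher and 2 lower of 9 (3 and 2 adjusted over the list alone, median 0.27, mean -0.36, camera direction up, Benjamini-Hochberg adjusted p = 0.799). Without A-DCC library 3 the fibroblast median was -0.14 with camera's direction still up (Benjamini-Hochberg adjusted p = 0.516), and the basal direction turned down at a median of 0.12 (adjusted p = 0.751). PDGFRB rose from 7.12 ± 0.166 to 27.9 ± 7.77 CPM and DCN fell from 1.3 ± 0.141 to 0.135 ± 0.0689 CPM. Leukocyte and endothelial lists had 4 measured members each and were not tested as lists. Leukocyte markers held 1 higher and 2 lower genes (1 and 2 adjusted over the list alone, and 2 and 2 with A-DCC library 3 left out), with LCP1 at 2.22 ± 0.637 CPM in DCC and 0 counts in A-DCC, at least 38.5-fold lower, and CD14 down from 2.62 ± 0.4 to 0.439 ± 0.152 CPM. Endothelial markers held 1 higher and 3 lower genes (1 and 3 adjusted over the list alone), with CDH5 up from 1.82 ± 0.564 to 13.6 ± 3.39 CPM and ESAM down from 41.2 ± 0.999 to 19.9 ± 2.17 CPM.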

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

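The list tests with an estimated correlation and A-DCC library 3 left out, and with length and GC correction, were chosen after the data were seen. The count of 8205 changed genes ranged from 6042 without DCC library 2 to 12056 without A-DCC library 3 when single libraries were left out, and from 6453 to 9343 under the other scalings, filters and tests. It was 3787 with a log2 fold change above 1 (1565 higher, 2222 lower) and 5429 at an adjusted p under 0.01 (2557 higher). Both follow from the stricter thresholds. Without A-DCC library 3, 8172 of the 8205 genes were called again, all in the same direction. The spread between libraries that edgeR estimated, as a coefficient of variation, was 0.175 with all libraries and 0.0436 without that library. The 14 lists were 14 under every scaling, the length and GC correction and 5 of the 6 left-out libraries, 11 without A-DCC library 3 and 17 with the 5 CPM filter. Fry's directional test, which asks whether a list moves at all, called 11 of the 14 among its 18 and lost G2/M (Benjamini-Hochberg adjusted p = 0.109), hypoxia (0.147) and ribosome biogenesis (0.172). Its mixed test, which takes changes in either direction, gave 29. Camera with an estimated correlation gave 0 (5 lists at an unadjusted p under 0.05), and 0 with A-DCC library 3 left out as well (4 lists at an unadjusted p under 0.05). The cause was not tested.

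The mean correlation between the groups, for the similarity of libraries, went from 0.916 to 0.409 over the 500 most variable genes, which were picked for differing, and to 0.9 with a prior count of 0.5. Of the 82 genes that the naming rule gave, 11 lost a call under an alternative and 0 reversed. Same-numbered libraries deviated from their group means with correlations of -0.0611, 0.0684 and 0.0146, against -0.0845 to 0.0697 for other pairs. A-DCC libraries 1 and 2 gave similar correlations with each DCC library, so this check cannot tell whether the numbers pair cultures. With the number as a replicate block 7332 genes (3527 higher, 3805 lower) and 14 lists were called, and not every library correlated best with its own number. In simulation with the spread of these libraries, A-DCC library 3 included, a 1.5-fold change was recovered for 25.4% of the better expressed genes that were given one.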

Other observations

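The gene families, the single genes in the next paragraphs, the depth test of the luminal markers, the test of the most counted genes and the test of DCC RNA in A-DCC library 3 were chosen after the results were seen.

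Of 20 gene families formed from symbols, the mitochondrial ribosomal proteins had the lowest camera p, with 37 of 77 higher and 4 lower in A-DCC, or 48 and 11 without A-DCC library 3 (median log2 fold change 0.46, camera, Benjamini-Hochberg adjusted p = 4.42e-05, and adjusted p = 0.514 with an estimated correlation). MRPS27 and MRPS9 rose by 1.85 and 1.47 on the log2 scale. Small nuclear ribonucleoproteins of the spliceosome had 10 of 20 higher and 0 lower, or 14 and 1 without that library (camera, Benjamini-Hochberg adjusted p = 0.00302, and adjusted p = 0.444 with an estimated correlation), among them SNRPD3 and SNRPD1. Translation initiation factors had 22 of 53 higher and 6 lower, or 30 and 12 without it (camera, Benjamini-Hochberg adjusted p = 0.0157, and adjusted p = 0.444 with an estimated correlation). S100 proteins, small calcium-binding proteins, had 1 of 12 higher and 8 lower, or 1 and 9 without it (camera, Benjamini-Hochberg adjusted p = 0.0216, and adjusted p = 0.439 with an estimated correlation). Of 15 matrix metalloproteinases 2, MMP7 and MMP24, rose and 8 fell, or 5 and 8 without it (camera, Benjamini-Hochberg adjusted p = 0.04, and adjusted p = 0.444 with an estimated correlation). Of 243 unannotated loci 41 rose and 82 fell, and without A-DCC library 3 these counts were 81 and 95. Over all 16613 tested features 4023 rose and 4182 fell. Unannotated loci held 0.063% of counts in A-DCC library 3, against 0.117% and 0.115% in A-DCC libraries 1 and 2. In DCC they held 0.0983% to 0.103%.

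TXNIP, a thioredoxin-binding protein induced by glucose, fell from 1799 ± 39.5 CPM in DCC to 19.5 ± 20.4 CPM in A-DCC (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000438). It lay at 7.52 and 7.88 CPM in A-DCC libraries 1 and 2 and at 43.04 CPM in library 3. STC1, the secreted hormone stanniocalcin 1, fell from 1855 ± 36.2 to 78.7 ± 57.2 CPM, and GJA1, the gap junction protein connexin 43, from 28.8 ± 0.643 to 0.135 ± 0.0895 CPM. TREM1, a myeloid receptor gene, had 931 counts in DCC and 3 in A-DCC, a ratio of 332 (95% interval 113 to 1610), and all 3 lay in A-DCC library 2, without which the group held 0 counts. The keratins of simple epithelium KRT7, KRT8 and KRT18 rose by 1.70 ± 0.18, 0.77 ± 0.20 and 0.86 ± 0.13 on the log2 scale.

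Of 9 luminal breast markers 7, ESR1 among them, lay under 2 CPM in all 6 libraries, although the labels say MCF7. Low depth is argued against, since 10 CPM would have been 158 counts in the shallowest library. MCF7 cells that had lost their luminal state would still lack CDKN2A and MTAP, which the line has deleted on both chromosomes, but the lowest CDKN2A level was 177 CPM and the lowest MTAP level was 59.8 CPM. These values argue against MCF7 cells, in either state, as the source of the 6 libraries. The candidate explanation that remains is that the libraries come from another cell line than the labels say. Both groups carry these values, and no test here shows which line it could be, nor whether both groups come from the same one.

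A-DCC library 3 differed at least 2-fold from the mean of A-DCC libraries 1 and 2 in 913 expressed genes. RNA from DCC mixed into it would move genes toward their DCC level, but 41.2% of these genes moved away from it, and genes nearly absent from A-DCC libraries 1 and 2 stood in library 3 at 0.368% of their DCC level (upper limit 0.724%). Shallower sequencing is argued against by its total of 18253231 counts, the highest of the 6, and by a gap in correlation that stayed at 0.0222 after thinning to one depth. Gene length and GC content explained 4.19% of the variance of the difference. Library 3 was lower in 680 of the 913 genes and higher in 233. It also had the fewest genes with at least 5 counts, 17097. Long noncoding RNA held 1.13% of its counts, against 1.87% and 1.86% in A-DCC libraries 1 and 2. The labels name nothing that sets this library apart, so no biological explanation was tested, and a difference in culture, harvest or library batch may remain.

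Most ribosomal protein and respiratory chain genes were higher in A-DCC. Neither list passed camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.227 and 0.18). Correcting each library for gene length and GC content left at least 123% of each list's median. The 10 most counted and the mitochondrial genes held 7.05% to 8.31% of the counts of a library, which can shift all other genes by at most 0.0197 on the log2 scale between any A-DCC and any DCC library, or 4.59% of the smaller list median. Reads shared with pseudogenes were not tested, and the difference between the cell states named by the groups may be the source but is itself untested.

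The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For changed genes, 1 of the 10 splits, the real one, gave as many, with 8205 genes against a highest other count of 0 in edgeR's quasi-likelihood test (16 to 489 genes at an unadjusted p under 0.05 in the other splits). For gene lists, 2 of the 10 splits gave as many, with 14 lists in the real split and 18 in the highest other. The other splits mix the groups unevenly. Part of the difference between the groups therefore remains in them, and part widens the spread within each side, which lowers the number of genes called. Their counts, the 0 for genes included, are not those of groups without a difference, so the contrast with 8205 decides nothing.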
